A study of Homo sapiens with 4 samples.

How the data were processed

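Total RNA of SCC-9 cells was measured on 4 Affymetrix PrimeView arrays, 2 of cells transfected with a miR-585-5p mimic and 2 of cells transfected with the control small RNA miR-NC. Per the labels' protocols, cells were transfected at 30 nM 24 hours after seeding, collected 36 hours later, and biotin-labelled RNA was prepared from 2 ug of total RNA. The values used are the deposited probe set intensities, for which the submitters' processing notes name RMA. RMA corrects background, normalizes between arrays and gives log2 values, but the deposited intensity values run from 2.09 to 17329 with medians near 31, so they were read as RMA output on a linear scale and their log2 was taken. Any floor or other filter applied before deposit is not given in the sources used here. Because RMA brings the arrays' probe intensities to 1 distribution, a change of the whole transcriptome in 1 direction cannot be seen on this scale. The arrays hold 49395 probe sets, of which 102 are controls. Probe sets were named through the platform annotation, in which 44988 have 1 gene symbol, 1832 have several and 2473 have none here, and the gene table of GRCh38.p14 changed 0 symbols. Probe sets with several symbols or none name no gene. Groups were taken from the sample titles.

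Each of 18132 genes took its brightest probe set over the 4 arrays, 11734 genes having several, and 14122 genes with a mean above the 30th percentile of the probe sets (intensity 12.0) were tested. The comparison, mimic minus control, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 8.35. The median SE of a log2 change was 0.10. All tests were two-sided. Errors of intensities are SDs and those of log2 changes are SEs. As background, 20 control probe sets with no human target were used, the highest at 16.8. A gene whose brightest probe set did not exceed them on any array of a group is given a bound, the mean of the other group over the higher of the brightest such control and the gene's own value on each array. Lists of genes were tested with camera (preset correlation 0.01, and estimated) and fry, with adjustment over the 34 lists. The test was tried on simulated data with 200 of the 14122 genes changed. It recovered 20% of genes changed 1.25-fold, 62% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. Of 149 calls 8 were on unchanged genes, and 0 genes were called when none was changed. Simulated genes varied independently, with spreads drawn from the fitted prior, so errors shared between genes were not tried. The adjustment is looser where far more genes change, so these shares do not carry over to the data.

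The comparison, the tests, the lists, the filter and the rule for named genes were fixed before the data were examined. The rule takes the 12 highest and 12 lowest log2 changes among genes past the threshold whose 2 mimic arrays lie on the same side of both control arrays, up to 4 changed members of each list with the largest change, and SLIT3, GAPDH and ACTB, and 1 of the 12 lowest is not reported here. Alternatives tried were a second quantile normalization, a shared median, other filters, other choices of probe set, other estimates of the spread, the replicate number as a block, other thresholds, a plain t-test, and leaving out each array. Scaling to the hybridization spikes (9 probe sets) or the poly(A) spikes (11 probe sets) and a filter at the no-target controls were added after seeing the data. A planned test of genes with sites for the microRNA seed was not run, because no transcript sequences were used here. Genes absent from the annotation used are not reported here.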

Results

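SCC-9 cells, a human line from a squamous carcinoma of the tongue, were transfected with a mimic of the microRNA miR-585-5p or with a control small RNA, miR-NC, each at 30 nM. RNA was collected 36 hours after transfection and measured on a PrimeView human gene expression array, with 2 arrays per group and 49395 probe sets per array. The comparison asks which transcripts of these tongue cancer cells differ when miR-585-5p is supplied in excess. Median intensities were 31.1 and 30.6 on the mimic arrays and 31.3 and 30.7 on the control arrays. Arrays of the same group correlated at 0.998 (mimic) and 0.997 (control) across probe sets, which are not independent replicates, and arrays of different groups at 0.978 to 0.982. The SD of the log2 difference between arrays was 0.178 and 0.211 within groups and 0.483 to 0.539 between groups. The 3' to 5' ratio of GAPDH, a sign of RNA integrity, was 1.11 on both mimic arrays and 1.22 and 1.16 on the control arrays, while that of ACTB was 14.3 on both mimic arrays and 14.4 and 13.8 on the control arrays, far above 1 in both groups. The poly(A) spikes, bacterial RNAs added before labelling, averaged 0.35 higher (log2) on the mimic arrays, while the hybridization spikes differed by -0.05. By spike the difference was 0.37 (dap), 0.48 (phe), 0.42 (lys) and 0.08 (thr). The 2 control arrays also differed from each other, with phe at 4.77 and 5.15 and lys at 4.75 and 5.02 (log2). The size of the offset is therefore uncertain. The labels do not say that the arrays of a group come from separate cultures, so p-values measure only the spread between these samples, which can be technical. The number of arrays limits the precision.

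No probe set measures the transfected microRNA, so its level could not be checked on these arrays. Its gene, MIR585, lies within the span of SLIT3, which encodes a secreted axon guidance ligand, in the GRCh38.p14 gene table. SLIT3 read 87.2 and 84.8 on the mimic arrays and 25.1 and 28.5 on the control arrays. It rose by 1.68 ± 0.12 on the log2 scale (SE, n = 2 per group, limma adjusted p = 6.76e-07). The mimic is an added oligonucleotide, so SLIT3 checks nothing about its uptake.

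The highest changes among genes past the threshold included several genes of cell division and a chemokine. NEK2, a centrosomal mitotic kinase, read 448 ± 9.93 in the mimic group and 41.1 ± 3.76 in the control group (intensity, SD, n = 2), a 10.9-fold rise (limma adjusted p = 2.17e-09). GLO1, which detoxifies methylglyoxal, read 1693 ± 6.55 against 157 ± 7.86, and the chemokine CCL20 1365 ± 135 against 140.5 ± 1.56. The mitotic kinase PBK rose 9.42-fold, the chromatin protein HMGA2 9.36-fold, cyclin A2 (CCNA2) 8.49-fold and the cytokinesis protein anillin (ANLN) 8.31-fold. The endoplasmic reticulum oxidase ERO1A rose 8.13-fold, the protease inhibitor TFPI2 7.66-fold and the carbonic anhydrase CA12 7.51-fold. NEURL1B, a ubiquitin ligase acting on Notch ligands, and GNAZ, a G protein subunit, were at the level of the probe sets with no human target in the control group and were at least 7.30-fold and at least 5.55-fold higher in the mimic group. Of the 3 other HMGA2 probe sets above background, 1 rose and 1 fell. Each of these 12 genes had an adjusted p of 7.13e-07 or less.

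Among the lowest changes, NF2, which encodes merlin, an upstream regulator of the Hippo pathway, read 71.6 ± 13.1 in the mimic group and 696 ± 17.1 in the control group, a 9.80-fold fall (limma adjusted p = 5.54e-09). DSEL, a relative of dermatan sulfate epimerase, fell 8.24-fold, and the ganglioside activator GM2A 5.86-fold. The actin-binding coronin CORO1C fell 5.36-fold, the reductase CYB5R3 5.32-fold and the membrane protein SMAGP 5.06-fold. The kinase OXSR1 fell 4.94-fold, the ubiquitin ligase adaptor KLHL7 4.79-fold and the imprinted gene MEST 4.78-fold. LRRC7 and the small heat shock protein HSPB3 were at the level of the probe sets with no human target in the mimic group and were at least 5.00-fold and at least 3.81-fold lower there. Some of these sizes belong to the brightest probe set of the gene. The mean of all probe sets also counts those not above background, which can draw it towards 0. With the mean of all probe sets, the log2 changes were HMGA2 0.63, GNAZ 1.65 and CA12 1.90 among the risen genes and NF2 -1.10, GM2A -1.57, CORO1C -0.92, CYB5R3 -1.59, OXSR1 -1.42, KLHL7 -0.60 and MEST -0.82 among the fallen ones, and without cross-hybridizing probe sets GLO1 was at 1.73, CORO1C at -0.49 and GM2A at -1.57.

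**Figure D1:**
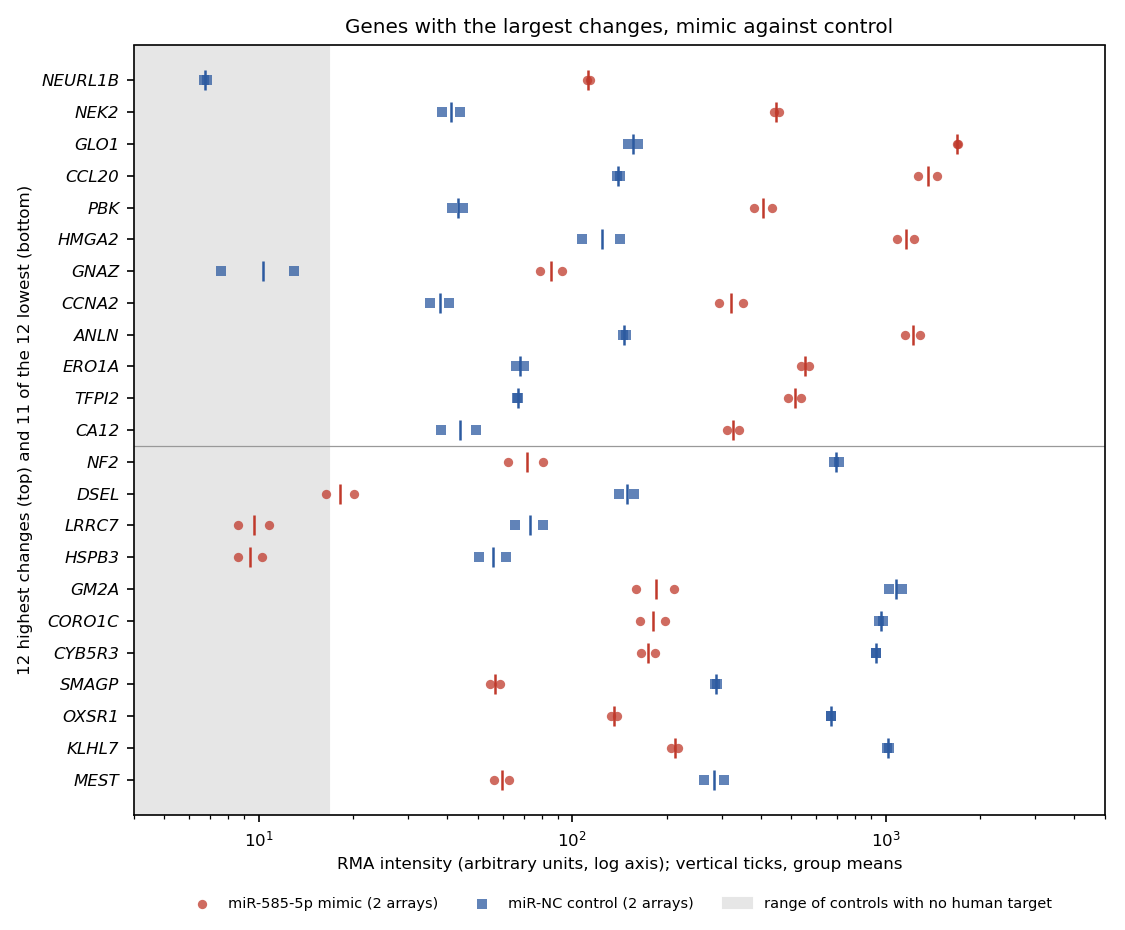
Intensity on each of the 4 arrays (horizontal log axis, arbitrary units) of the 12 genes with the highest and 11 of the 12 with the lowest log2 change, with circles for the mimic group, squares for the control group, vertical ticks for group means and a grey band for the range of control probe sets with no human target. For every gene both mimic arrays lie on the same side of both control arrays, and NEURL1B and GNAZ in the control group and LRRC7 and HSPB3 in the mimic group lie within the grey band.

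Over all genes, 7768 of 14122 changed, 3966 of them higher and 3802 lower in the mimic group, at a limma adjusted p under 0.05. Changes of at least 2-fold numbered 672 higher and 481 lower, and changes of at least 4-fold 78 higher and 23 lower. Both mimic arrays lay on the same side of both control arrays for 79.4% of the genes tested, where chance gives 33.3%. The balance of directions rests on the scaling: with the arrays set to the poly(A) spikes, a setting chosen after seeing the data, 1613 genes were higher and 8200 lower, so that 16.4% of the calls were higher against 51.1% on the deposited scale. That scaling rests on an average over spikes that differ, from 0.08 for thr to 0.48 for phe. It lowers every gene alike and moves the median log2 change of all genes from -0.06 to -0.40. The changes given here are on the deposited scale, relative to the array as a whole. Without mimic replicate 2 the count of lower genes was 2509 and the whole count 5406. GAPDH rose by 0.15 ± 0.03 and ACTB by 0.34 ± 0.10, and with the poly(A) spikes they were at -0.20 and -0.01. Neither passed without mimic replicate 2 (0.14 and 0.29), nor ACTB without mimic replicate 1 (0.39), and ACTB was at 0.15 without control replicate 1 and 0.53 without control replicate 2, and at 0.22 with the mean of all probe sets.

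Of the 34 gene lists fixed before the data were examined, 6 were shifted against the other genes by camera with a preset correlation of 0.01, 4 higher and 2 lower in the mimic group. None of the 6 passed with the correlation estimated from these 4 arrays, so each shift is given with both p-values. With an estimated correlation camera uses the 2 residual degrees of freedom, so hardly any of 34 lists could pass. The fatty acid list went from an unadjusted camera p = 3.67e-05 to 0.0482, though its estimated correlation was -0.054, under the preset 0.01. A miss there decides little, while the preset version assumes that members vary almost independently. Log2 changes of named members are given ± SE, from 2 arrays per group. Averaging all probe sets of a gene moved 50 of the named genes by over 1.5 times, and leaving out cross-hybridizing ones moved 19. The average takes in probe sets not above background, so a smaller value need not mean that probe sets disagree. For 13 named genes none of the other probe sets above background passed: TP53INP1, BCL2L2, BMF, CASP8, TWIST2, SOX15, ERBB3, DLL1, MAML1, FGFR3, RPL22, RPL18 and CSF1R. In some genes another probe set above background passed in the opposite direction, among them HMGA2 (1 of 3 others), INPP4B (1 of 4), BCL2L1 (1 of 2) and DSP (1 of 1). Counts of changed members use the test over all genes, and members named beyond the 4 largest changes of a list were chosen after their values were seen.

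Mitotic genes rose together. All 28 genes of the G2/M list rose (28 adjusted over the list alone), with a median log2 change of 1.78, 1.83 above the median gene. Besides ANLN, the largest were TOP2A, which decatenates chromosomes, at 2.86 ± 0.06 (SE), the kinetochore protein NDC80 at 2.66 ± 0.09 and the centromeric histone CENPA at 2.38 ± 0.08. The proliferation marker MKI67 was at 1.96 ± 0.09 and cyclin B1 (CCNB1) at 2.12 ± 0.07. The list had a camera adjusted p = 1.13e-18, and adjusted p = 0.668 with an estimated correlation. Of 29 genes of G1/S and DNA replication, 25 rose and none fell (26 adjusted over the list alone). CCNA2 led them at 3.09 ± 0.11, followed by thymidylate synthase (TYMS) at 1.94 ± 0.06, the sliding clamp PCNA at 1.58 ± 0.08 and GINS2, of the replicative helicase, at 1.54 ± 0.10, while E2F1 0.38, MCM5 0.15, POLE 0.06 and E2F2 -0.16 did not pass. This list had a median of 0.97 (log2) and a camera adjusted p = 1.34e-10, and adjusted p = 0.668 with an estimated correlation. With the poly(A) spikes its median was 0.62, and PCNA with the mean of its probe sets 0.66.

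DNA repair genes rose in part. Of 19, 13 rose and 3 fell (16 adjusted over the list alone), with a median of 0.61. BRCA1 rose 2.82-fold, the helicase BLM by 1.43 ± 0.16 on the log2 scale and RAD54L, which acts in homologous recombination, by 1.23 ± 0.15. Those that fell were the single-strand break scaffold XRCC1 at -1.33 ± 0.10, RAD52 at -0.59 and PALB2 at -0.33. The list had a camera adjusted p = 0.0260, and adjusted p = 0.713 with an estimated correlation. Its call ended with genes above the 50th percentile alone (adjusted p = 0.0698), its median was 0.26 with the poly(A) spikes, and XRCC1 did not pass without cross-hybridizing probe sets (-0.29). BRCA1 and XRCC1 were at 0.89 and -0.73 (log2) with the mean of all probe sets, and BRCA1 at 0.83 without cross-hybridizing ones.

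Signals of most histone genes of the replication-dependent clusters fell. Whether these signals follow the total amount of histone transcripts was not tested. Of 10, 7 fell, led by H1-2 -1.70 ± 0.07, H3C4 -1.18 ± 0.14, H2AC6 -0.93 ± 0.10 and H2AC8 -0.91 ± 0.09, and 2 rose, H4C3 0.41 and H2BC9 0.56 (9 adjusted over the list alone). The list missed the threshold (camera adjusted p = 0.0533, and 0.668 with an estimated correlation). It passed with the poly(A) spikes (camera adjusted p = 0.0147) and with fry (adjusted p = 0.0129), which 17 of the 34 lists passed. Regulators of the G1 phase were mixed: of 13, 7 rose and 4 fell (12 adjusted over the list alone, camera adjusted p = 0.316). The CDK inhibitor CDKN1C (p57) rose by 2.35 ± 0.07 and the transcription factor E2F3 by 1.07 ± 0.11. The CDK inhibitor CDKN1A (p21) went from 4377 ± 41.3 to 1645 ± 48.7, a change of -1.41 ± 0.04, and cyclin D3 (CCND3) fell 2.84-fold, with CDKN2B at -0.85 and CDK2 at -0.35. Among 18 targets of p53, 6 rose and 8 fell (14 adjusted over the list alone, camera adjusted p = 0.737). CDKN1A, TP53I3 (-1.12 ± 0.08) and the secreted factor GDF15 (-1.03 ± 0.08) fell, and TP53INP1 rose by 1.13 ± 0.10. With the mean of all probe sets, CCND3 was at -0.69 and TP53INP1 at 0.38.

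Lipid synthesis genes mostly fell. In the cholesterol pathway 14 of 18 genes fell and 2 rose (16 adjusted over the list alone), with a median log2 change of -0.64. The sterol-sensing transcription factor SREBF2 went from 264 ± 10.8 to 108 ± 3.79 (intensity, SD, n = 2), a change of -1.29 ± 0.08, and the enzymes DHCR7, MVD and SC5D were at -1.26 ± 0.08, -1.21 ± 0.07 and -1.15 ± 0.07. The risen genes were FDPS 0.59 and STARD4 0.47, an isoprenoid synthase and a sterol carrier. The list had a camera adjusted p = 3.29e-04, and adjusted p = 0.668 with an estimated correlation. Of 14 fatty acid synthesis genes, 10 fell and none rose (10 adjusted over the list alone), with a median of -0.40. The acetate-activating enzyme ACSS2 fell by 2.17 ± 0.07, fatty acid synthase (FASN) by 1.39 ± 0.06, the desaturase FADS1 by 0.98 ± 0.07 and acetyl-CoA carboxylase (ACACA) by 0.79 ± 0.07. This list had a camera adjusted p = 3.12e-04, and adjusted p = 0.668 with an estimated correlation. With the poly(A) spikes the medians were -0.98 and -0.74. ACACA was at -0.51 with the mean of all probe sets, and SC5D at -1.98 without cross-hybridizing ones.

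Genes of hypoxia and glycolysis mostly rose, 22 of 26, with 3 falling (26 adjusted over the list alone) and a median of 0.39. NDRG1, a hypoxia-induced stress gene, rose by 1.28 ± 0.05, the prolyl hydroxylase EGLN3 by 1.22 ± 0.16, the mitophagy receptor BNIP3 by 1.15 ± 0.04 and ANKRD37 by 0.99 ± 0.08. The fallen genes were pyruvate kinase (PKM) at -0.63, PFKFB4 at -0.53 and triosephosphate isomerase (TPI1) at -0.28. The list had a camera adjusted p = 2.50e-05, and adjusted p = 0.668 with an estimated correlation. With the poly(A) spikes its median was 0.04, which is 0.44 above the median gene, as on the deposited scale. The changes of EGLN3 0.70, BNIP3 0.58 and ANKRD37 0.52 with the mean of all probe sets were smaller, though none of these genes had another probe set above background. In oxidative phosphorylation 5 of 30 genes rose and 7 fell (11 adjusted over the list alone, camera adjusted p = 0.862). The complex III core subunits UQCRC2 and UQCRC1 fell by 1.31 ± 0.05 and 1.24 ± 0.05, beside smaller changes of the complex I subunits NDUFB5 (0.57 ± 0.05) and NDUFA8 (-0.48 ± 0.05). The other risen genes were NDUFB3 0.33, NDUFS4 0.21, COX6C 0.19 and NDUFA9 0.18.

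Stress responses split within their lists. Of 22 genes of the unfolded protein and ATF4 response, 9 rose and 9 fell (18 adjusted over the list alone, camera adjusted p = 0.862). The serine synthesis enzymes PSAT1 (1.43 ± 0.08) and PHGDH (2.38-fold) and the chaperone PDIA4 (1.21 ± 0.10) rose, while the transcription factor ATF3 was at -1.05 ± 0.09. Among 19 NRF2 targets 6 rose and 8 fell (15 adjusted over the list alone, camera adjusted p = 0.862). The aldo-keto reductases AKR1C1 and AKR1C3 rose by 1.38 ± 0.17 and 0.80 ± 0.11, and heme oxygenase (HMOX1) and thioredoxin reductase (TXNRD1) were at -1.23 ± 0.12 and -0.88 ± 0.05. Averaging all probe sets, ATF3 was at -0.45, HMOX1 at -0.81 and AKR1C3 at 0.34.

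Mesenchymal and epithelial genes changed in part, and neither list passed camera on the deposited scale. Both passed fry (adjusted p = 0.00381 and 0.0388), as 17 of the 34 lists did. With the poly(A) spikes the epithelial list passed camera (adjusted p = 0.0149) and the mesenchymal list did not (adjusted p = 0.134). Of 17 mesenchymal genes 10 rose and 3 fell (13 adjusted over the list alone, camera adjusted p = 0.0676). The collagen cross-linking enzyme LOX rose by 1.04 ± 0.09, fibrillin (FBN1) by 0.99 ± 0.13, the intermediate filament vimentin (VIM) by 0.97 ± 0.05 and TWIST2 from 216 ± 16.8 to 433 ± 17.9 in intensity, though its log2 change was -0.33 without cross-hybridizing probe sets. The fallen genes were COL1A1 -0.47, SPARC -0.37 and TWIST1 -0.21. Of 25 genes of epithelial junctions 4 rose and 11 fell (15 adjusted over the list alone, camera adjusted p = 0.0676). E-cadherin (CDH1) went from 1916 ± 124 to 801 ± 19.6, a change of -1.26 ± 0.06, with claudin CLDN4 at -1.03 ± 0.09, plakoglobin (JUP) at -0.78 ± 0.06 and the epithelial transcription factor OVOL1 at -0.65 ± 0.06. The risen ones were EPCAM 0.59, CDH3 0.26, DSP 0.25 and PKP3 0.21, though the 1 other DSP probe set above background fell. TWIST2 was at 0.34 and OVOL1 at -0.37 with the mean of all probe sets.

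Among 12 genes of basal squamous identity 5 rose and 4 fell (9 adjusted over the list alone, camera adjusted p = 0.862). The basal keratin KRT14 rose by 0.97 ± 0.05, while the hemidesmosomal integrin ITGB4 was at -1.11 ± 0.07, TRIM29 at -0.97 ± 0.06 and SOX15 at -0.58 ± 0.05. The other risen genes were ITGA6 0.50, PITX1 0.40, KRT15 0.29 and KRT5 0.24, and TFAP2A fell (-0.33). Of 23 genes of keratinocyte differentiation 4 rose and 8 fell (12 adjusted over the list alone, camera adjusted p = 0.862). The calcium-binding protein S100A9 rose by 0.99 ± 0.08, beside S100A8 0.41, KLF4 0.38 and KRT10 0.20, and the cornified envelope genes SPRR1B, CRCT1 and IVL were at -0.59 ± 0.07, -0.54 ± 0.11 and -0.42 ± 0.14. Of 23 invasion proteases and integrins 8 rose and 9 fell (17 adjusted over the list alone, camera adjusted p = 0.862). The matrix metalloproteinases MMP7 and MMP13 were at -1.72 ± 0.08 and -1.19 ± 0.11, MMP12 was at least 2.07-fold lower, at background in the mimic group, and the sheddase ADAM9 rose by 1.47 ± 0.09. IVL did not pass without mimic replicate 1 (-0.43), mimic replicate 2 (-0.40) or control replicate 2 (-0.34). SOX15 and MMP13 were at -0.31 and -0.76 with the mean of all probe sets.

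In signalling pathways, targets of YAP and TAZ fell more often than they rose, 13 against 4 of 23 (18 adjusted over the list alone), with a camera adjusted p = 0.0945. AMOTL2, MYOF and DLC1 were at -1.08 ± 0.07, -0.78 ± 0.04 and -0.77 ± 0.13, and the risen genes were the coagulation starter F3 at 1.17 ± 0.07 with FJX1 0.68, NT5E 0.47 and GADD45A 0.46. Of 19 TGF-beta targets and components 7 rose and 7 fell (15 adjusted over the list alone, camera adjusted p = 0.862). The receptor TGFBR1 rose by 1.27 ± 0.08 and LTBP1 by 0.81 ± 0.10, SKIL was at least 1.45-fold higher, and ID2 was at -0.79 ± 0.09. Of 25 genes of EGFR and MAPK output 14 rose and 4 fell (18 adjusted over the list alone, camera adjusted p = 0.0650). The ERK phosphatase DUSP6 and the transcription factor ETV5, both induced by ERK, rose by 1.46 ± 0.07 and 1.24 ± 0.11. The fallen genes were receptors and a ligand: ERBB3 -1.53, TGFA -1.15, ERBB2 -0.62 and EGFR -0.29. ERBB3 was at 0.03 without cross-hybridizing probe sets, and TGFBR1 at 0.43. Averaging all probe sets put ERBB3 at -0.69, TGFBR1 at 0.60 and TGFA at -0.54.

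Of 18 genes of the PI3K and mTOR list 10 rose and 4 fell (14 adjusted over the list alone, camera adjusted p = 0.0918). The list holds PDK1, a pyruvate dehydrogenase kinase outside that pathway, which rose by 1.69 ± 0.18, and of the 17 others 9 rose and 4 fell. The S6 kinase RPS6KB1 rose by 1.06 ± 0.09 and the phosphatase INPP4B by 0.85 ± 0.07, and AKT2 -0.74, IRS1 -0.56, AKT1 -0.52 and EIF4EBP1 -0.26 fell. Of 19 Wnt targets and components 10 rose and 6 fell (17 adjusted over the list alone, camera adjusted p = 0.737). The coreceptor LRP6 rose by 1.36 ± 0.10, while SOX9, the Wnt antagonist DKK1 and the ligase RNF43 were at -1.77 ± 0.07, -1.24 ± 0.05 and -0.85 ± 0.09. Of 17 Notch pathway genes 8 rose and 5 fell (13 adjusted over the list alone, camera adjusted p = 0.862). The ligand DLL1 rose by 0.96 ± 0.10, and MAML2, NOTCH2, MAML1, NOTCH1 and HEYL were at -1.37, -0.96, -0.88, -0.54 and -0.34. DLL1 did not pass with the mean of its probe sets (0.16), nor MAML1 without cross-hybridizing ones (-0.24). Other changes shrank while passing: with the mean, RPS6KB1 0.56, INPP4B 0.40, AKT2 -0.45, RNF43 -0.46, NOTCH2 -0.60 and MAML1 -0.56, and without cross-hybridizing probe sets AKT2 -0.44, LRP6 0.71 and SOX9 -0.90.

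Of 25 genes recurrently altered in head and neck cancer 10 rose and 7 fell (18 adjusted over the list alone, camera adjusted p = 0.927). The Hippo effector YAP1 went from 2604 ± 19.6 to 821 ± 70.9, a change of -1.67 ± 0.06, the receptor tyrosine kinase MET from 863 ± 5.64 to 291 ± 9.43, a change of -1.57 ± 0.06, and the receptor FGFR3 rose by 1.37 ± 0.10. With the mean of all probe sets these were -0.87, -0.60 and 0.57, and without cross-hybridizing probe sets YAP1 was at -0.66, each still past the threshold.

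Inflammatory genes held some of the largest single changes. Of 22 genes of NF-kB and cytokines 10 rose and 4 fell (15 adjusted over the list alone, camera adjusted p = 0.177). Besides CCL20, the chemokine CXCL10 rose by 2.40 ± 0.24 with a wide spread between its mimic arrays (202 ± 94.5 against 36.2 ± 0.381), and the NF-kB inhibitor TNFAIP3 rose by 1.63 ± 0.15. Cyclooxygenase (PTGS2) was at -1.90 ± 0.13, and ICAM1, TNFAIP2 and LIF were at -0.81, -0.34 and -0.29. Among 21 interferon response genes 7 rose and 4 fell (13 adjusted over the list alone, camera adjusted p = 0.734). The RNA sensor RIGI, IFIT1, MX1 and MX2 rose by 1.06 ± 0.11, 1.03 ± 0.11, 0.91 ± 0.15 and 0.84 ± 0.16, and IFI6 -0.76, EIF2AK2 -0.63, IRF9 -0.53 and IFIT5 -0.36 fell. PTGS2 was at -1.03 and MX2 at 0.35 with the mean of all probe sets.

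Of 21 genes of the small RNA machinery 11 rose and 5 fell (16 adjusted over the list alone, camera adjusted p = 0.0822). The Argonautes AGO3 and AGO4 and the silencing scaffolds TNRC6A and TNRC6B rose by 1.10 ± 0.07, 0.88 ± 0.12, 0.68 ± 0.07 and 0.65 ± 0.08, and CNOT6 -0.42, AGO1 -0.39, DGCR8 -0.36, CNOT6L -0.36 and CNOT1 -0.24 fell. Among 19 chromatin writers and erasers 7 rose and 4 fell (11 adjusted over the list alone, camera adjusted p = 0.807). The maintenance methyltransferase DNMT1 rose by 0.53 ± 0.06 and the histone methyltransferase EZH2 was at least 1.18-fold higher, while TET3 -0.71, TET2 -0.60, TET1 -0.53 and KDM1A -0.48 fell. With the poly(A) spikes neither DNMT1 (0.19) nor EZH2 (0.43) passed, nor did EZH2 without mimic replicate 2 (0.65). Of 21 apoptosis regulators 7 rose and 5 fell (12 adjusted over the list alone, camera adjusted p = 0.905). The survival factor BCL2L2 was at -2.04 ± 0.06 and the BH3-only protein BMF at -1.77 ± 0.11, with HRK -0.68, BCL2L1 -0.35 and BAK1 -0.22. BID rose by 0.73 ± 0.07 and caspase CASP8 by 0.70 ± 0.10, though CASP8 was at -0.18 without cross-hybridizing probe sets, and none of the 2 other probe sets above background of BCL2L2, nor of the 2 of BMF, passed. The changes with the mean of all probe sets were BCL2L2 -0.85, BMF -0.62 and TET3 -0.38, and without cross-hybridizing ones TNRC6A 1.08 and TNRC6B 0.41.

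Ribosomal protein genes changed little on the deposited scale, apart from RPL14, and their median was -0.34 with the poly(A) spikes. RPL14 went from 9922 ± 138 to 2547 ± 109.9 (intensity, SD, n = 2), a change of -1.96 ± 0.04 (limma adjusted p = 1.20e-09), while the 38 other ribosomal protein genes lay between -0.11 and 0.34. Of 39, 3 rose and 3 fell (3 adjusted over the list alone, camera adjusted p = 0.905). RPL7, RPL22 and RPL18 rose by 0.34 ± 0.05, 0.15 ± 0.03 and 0.12 ± 0.03 on the deposited scale and were at -0.01, -0.20 and -0.23 with the poly(A) spikes, and RPS27 -0.11 and RPL3 -0.09 fell. Without cross-hybridizing probe sets RPL14 rested on a single probe set at background and was at -0.08. RPL22 and RPL18 did not pass without mimic replicate 1 (0.14 and 0.11) or mimic replicate 2 (0.15 and 0.12), nor with the mean of all probe sets (0.0488 and 0.0372).

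Few markers of other cell types passed the test. Of 6 fibroblast markers FAP rose by 0.47 ± 0.11 and COL1A1 was at -0.47 ± 0.13 (2 adjusted over the list alone, camera adjusted p = 0.737). Of 6 endothelial markers KDR was at -0.73 ± 0.15 and the others did not pass (1 adjusted over the list alone, camera adjusted p = 0.734). Of 7 leukocyte markers CD14 and LAPTM5 rose by 0.68 ± 0.12 and 0.36 ± 0.13, and CSF1R was at -0.39 ± 0.13 (2 adjusted over the list alone, camera adjusted p = 0.905). Of 8 muscle and nerve markers SYP and STMN2 were at -0.41 ± 0.13 and -0.38 ± 0.14 (0 adjusted over the list alone, camera adjusted p = 0.436). Without mimic replicate 2 none of FAP 0.32, COL1A1 -0.49, CSF1R -0.42, LAPTM5 0.36, SYP -0.34 and STMN2 -0.29 passed (log2 changes), nor did the last 5 without mimic replicate 1 (COL1A1 -0.44, CSF1R -0.36, LAPTM5 0.36, SYP -0.48 and STMN2 -0.48). Without control replicate 1 LAPTM5 0.28, SYP -0.24 and STMN2 -0.40 did not pass, and without control replicate 2 CSF1R -0.33 and STMN2 -0.37 did not, nor did CSF1R -0.22 and SYP -0.21 with the mean of all probe sets, FAP 0.12 and LAPTM5 0.0145 with the poly(A) spikes, or LAPTM5 with no filter (adjusted p = 0.0529). The median, the mean and the test of a list differed in sign for p53 targets, apoptosis regulators, basal squamous identity, the Notch pathway, head and neck cancer genes, ribosomal proteins and oxidative phosphorylation.

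**Figure D2:**
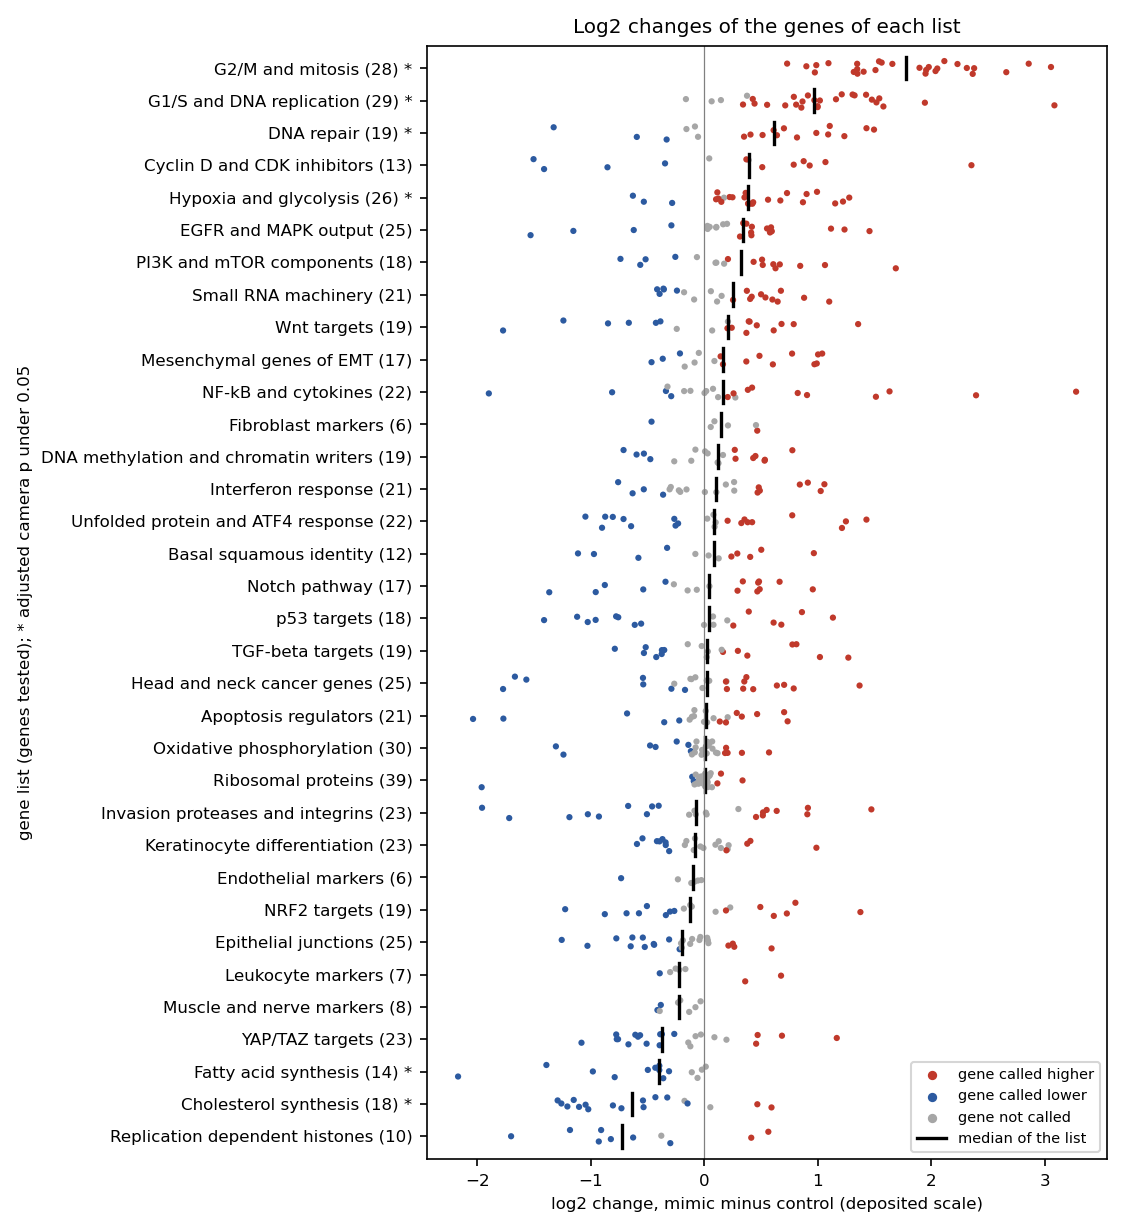
Log2 change, mimic minus control on the deposited scale (horizontal axis), of each tested gene of the 34 lists, sorted by median, with red points for genes called higher, blue for genes called lower, grey for the others and a black bar for the median of each list. All 28 points of the G2/M list lie above 0, the 14 points of the fatty acid list lie mostly below, and RPL14 at -1.96 stands apart from the other ribosomal proteins.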

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

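The tests in this part of cross-hybridizing and dim probe sets and of probe sets shared among ribosomal proteins were chosen before their results were seen, and the other tests after. Among probe sets outside the gene comparison, those with no gene here held 427 calls higher and 330 lower of 1543 tested. Those with several genes held 258 calls higher and 241 lower of 1210. A higher call means a higher mean log2 value in the mimic group than in the control group. No biological explanation was tested for them. Of the 3 splits of the 4 arrays into pairs, limma called 7768 genes in the real one and 0 in each of the other 2 (16 and 8 genes at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05, with 1 split as large as the real one, itself.

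The rise of the mitotic and replication genes in the mimic group was weighed first. Under 4 other scalings the lowest median of the G2/M list was 1.43, with the poly(A) spikes. A scaling that shifts a whole array cannot move a list against the other genes, and the list stayed 1.83 above the median gene. The test thus shows only that none of the offsets tried was large enough to produce the rise. Sparser cultures in the mimic wells would raise targets of YAP and TAZ, whose median was -0.37, with 4 higher and 13 lower, but YAP1 itself fell, which may lower them at any density and was not tested apart, so this stays open. Exchanged labels could not be tested, with 0 probe sets for the transfected RNA. An effect of the microRNA on the cell cycle is a hypothesis beside these open explanations.

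The fall of RPL14 beside small changes of the other ribosomal proteins was weighed next. A fault of a single probe set does not account for it, since 4 of the 4 RPL14 probe sets above the no-target controls fell at least 2-fold (log2 changes from -2.27 to -1.86), though these may share probes. A shift shared by cross-hybridizing probe sets of ribosomal proteins was not seen in the 63 such probe sets of the other genes, with a median of 0.021 and a range of -0.11 to 0.37. The 4 RPL14 probe sets that fell are themselves of the cross-hybridizing kind, and the remaining one, at background, was at -0.08. Whether the 4 also report another transcript was not tested. Direct repression by the mimic is untested, since no transcript sequences were used here.

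Probe sets of 1 gene moving in opposite directions were weighed last: of 4099 genes with several called probe sets, 504 (12.3%) had calls both ways. Cross-hybridization does not account for the share as a whole, which was 12.9% (311 of 2420) with probe sets meant to be specific to a gene. Nor does low signal, since the share was 12.1% (462 of 3808) above the no-target controls. Genes moving at least 2-fold each way numbered 8 with all probe sets and 4 with the specific ones, so cross-hybridization stays open for single genes. In 7 genes probe sets above those controls moved at least 2-fold each way: CANX, NUFIP2, SRSF10, H2AZ2, PCGF5, AGPS and TRIM44, chosen after their values were seen. The called probe sets of SRSF10 above those controls were all of the cross-hybridizing kind. A shift between transcript ends or isoforms may contribute, and no isoform sequences were used here to test it.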

How the results depend on the processing

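The scalings to spikes and the filter at the no-target controls were chosen after seeing the data, and the other settings before. Of the planned settings that keep all 4 arrays, a minimum fold of 2 left 1153 genes (672 higher, 481 lower), and a plain t-test 2911 (1449 higher, 1462 lower), and under the others counts ran from 6621 to 8778, within 1.5 times of 7768. The poly(A) spikes gave 9813, with 1613 higher and 8200 lower, and the hybridization spikes 58.0% higher calls. Leaving out 1 array gave 5406 to 8128 genes, 2897 to 4087 higher and 2509 to 4041 lower, the lowest counts without mimic replicate 2, where the lone mimic array was assumed to vary like the control arrays. Lists past the threshold numbered 6, 10 with no filter, 0 with the estimated correlation (1 at an unadjusted p under 0.05), 17 with fry, 9 with the poly(A) spikes and 7 to 9 with 1 array left out, and 5 to 8 under the others. The replicate block gave 8253 genes (4132 higher, 4121 lower) and 7 lists. The labels share only a number between groups, and deviations of same-numbered arrays correlated at 0.084.

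None of the 6 shifted lists reversed under any setting run. The cause of the following reversals of list medians was not tested, apart from the scaling itself. With the poly(A) spikes, which lower the change of every gene alike, so that the reversals follow from the shift alone, they were p53 targets -0.31, Apoptosis regulators -0.33, Mesenchymal genes of EMT -0.18, Basal squamous identity -0.26, TGF-beta targets -0.32, EGFR and MAPK output -0.00198, PI3K and mTOR components -0.0245, Wnt targets -0.14, Notch pathway -0.30, Interferon response -0.24, NF-kB and cytokines -0.18, Unfolded protein and ATF4 response -0.26, Small RNA machinery -0.0927, DNA methylation and chromatin writers -0.23, Head and neck cancer genes -0.32, Ribosomal proteins -0.34, Oxidative phosphorylation -0.34 and Fibroblast markers -0.20. Quantile normalized again, they were p53 targets -0.00579, Apoptosis regulators -0.0372, TGF-beta targets -0.0441, Head and neck cancer genes -0.0197, Ribosomal proteins -0.0241 and Oxidative phosphorylation -0.0478. With the mean of all probe sets they were Apoptosis regulators -0.0838, TGF-beta targets -0.0314, DNA methylation and chromatin writers -0.0496, Head and neck cancer genes -0.0350 and Oxidative phosphorylation -0.00457, and without _x_at and _s_at probe sets Apoptosis regulators -0.0466, Invasion proteases and integrins 0.14, Head and neck cancer genes -0.11 and Ribosomal proteins -0.0278. With no filter they were Notch pathway -0.0105 and Interferon response -0.0618. With the 50th percentile and the no-target filter the invasion list (Invasion proteases and integrins) was at 0.0172 and 0.0140. Leaving out 1 array, medians ranged as follows: p53 targets -0.00337 to 0.0236, Apoptosis regulators -0.0150 to 0.0308, Invasion proteases and integrins -0.0746 to 0.00780, TGF-beta targets -0.0528 to 0.0114, Notch pathway -0.0160 to 0.11, Interferon response -0.0986 to 0.18, Head and neck cancer genes -0.0104 to 0.0977, Ribosomal proteins -0.0139 to 0.0104 and Oxidative phosphorylation -0.00939 to 0.0127.

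Among named genes, CASP8 -0.18, TWIST2 -0.33 and ERBB3 0.0309 reversed without _x_at and _s_at probe sets, and RPL7 -0.00909, RPL22 -0.20, RPL18 -0.23, ACTB -0.00571 and GAPDH -0.20 with the poly(A) spikes. With the mean of all probe sets, 50 named genes moved by over 1.5 times, and DLL1 0.16, RPL22 0.0488, RPL18 0.0372, CSF1R -0.22 and SYP -0.21 no longer passed. Without a trend RPL22 0.15, RPL18 0.12, ACTB 0.34 and GAPDH 0.15 did not pass, nor did IVL -0.36, CSF1R -0.34 and STMN2 -0.33 with the hybridization spikes or RPL18 0.0583 and STMN2 -0.32 quantile normalized again. Signal over background limits 296 tested genes, whose brightest probe set lay at or under the no-target controls in both groups. The seed-match test and its alternatives were not run, because no transcript sequences were used here.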

Other observations

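All tests in this part followed from patterns seen in the data. The test on NF2 was chosen after its result was seen, and its rule was then changed to leave the release open where YAP1 itself fell, and the 3 tests of microRNA target lists were chosen before theirs. Loss of merlin, the product of NF2, is known to release YAP and TAZ, so a release was a candidate explanation to test where NF2 fell by 3.29 on the log2 scale. That is its brightest probe set. With the mean of all probe sets NF2 was at -1.10, and its 3 other probe sets above background fell too. The targets of YAP and TAZ instead had a median of -0.37, with 4 higher and 13 lower, so a release was not seen. It stays open, since YAP1 itself fell, which may lower them with or without merlin and was not tested apart.

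HMGA2, a known target of let-7, rose 9.36-fold by its brightest probe set, and by 0.63 (log2) with the mean of all probe sets. Of its 3 other probe sets above background, 1 rose and 1 fell. A mimic in excess may displace endogenous microRNAs from Argonaute proteins. Of 28 let-7 targets other than HMGA2, 11 rose and 6 fell (median 0.059, camera p = 0.219, 0.30 with an estimated correlation). GNG5 and ACVR1C rose by 1.88 and 2.44, while IGF2BP1 was at -1.68. Of 16 miR-21 targets 10 rose and 2 fell (median 0.35, camera adjusted p = 0.00453 over 3 lists). The rises were led by YOD1 at 1.64, NFIB at 1.26 and the tumour suppressor PDCD4 at 0.97, with TIMP3 and MARCKS lower. The fall of TIMP3 is that of its brightest probe set, while its 2 other probe sets above background rose. With an estimated correlation, on 2 residual degrees of freedom, camera p = 0.226 for this list, and 5 of its genes are also in the lists fixed before. Of 16 miR-17 family targets 2 rose and 6 fell (median -0.057, camera p = 0.305, 0.386 with an estimated correlation), CDKN1A falling most. The poly(A) spikes, which were not tried on these 3 lists, differ between groups by 0.35 (log2), about as much as the miR-21 median. The miR-21 targets fit displacement with the preset correlation on the deposited scale alone, and the let-7 and miR-17 tests do not decide, so displacement stays a hypothesis. These genes were named after their values were seen.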
